A study of Caenorhabditis elegans with 15 samples.

How the data were processed

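RNA from young adult Caenorhabditis elegans was sequenced in 15 libraries. The 5 genotypes, with 3 libraries each, were N2, which is the common laboratory wild type, and the puf-8 alleles ust221, ust222, ust223 and ok302. PUF-8 is a Pumilio/FBF-family RNA-binding protein that acts on the 3' UTRs of mRNAs. The labels give the alleles by name and add short codes for the 3 ust alleles that are not interpreted here. Per the labels' protocols, animals synchronised as first-stage larvae grew on Escherichia coli OP50 at 20 °C, RNA was extracted with TRIzol, treated with a phosphatase and a polynucleotide kinase, selected with poly-T beads and made into libraries with the NEBNext Ultra kit.

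The authors deposited 1 table of raw read counts per gene for the 15 libraries, with gene identifiers, coordinates and descriptions. HISAT2 2.0.5 is named in the submitters' processing notes. The program that counted the reads, its setting for reads that match several genes or for strand, the genome build and the annotation are not given in the sources used here. The deposited counts were whole numbers with a different sum in each library, from 20969800 to 29352254 reads. Of the 47111 genes in the table, 46904 had WormBase identifiers and 207 had none. Those 207 held at most 0.0475% of the counts of a library. Symbols came from a table of gene names, which matched 44017 identifiers; 3094 had no symbol. The reference annotation at hand (Ensembl release 115) held 46817 of the identifiers, all on the same chromosome as in the deposited table, and 69.1% of them with the same start and end. Coordinates are printed as the deposited table gives them, without a build name. No reads, UMIs or strand information were used, so counts of overlapping genes, antisense genes and near-identical gene copies are uncertain. Copies of this kind include the major sperm proteins, replication histones, vit-3, vit-4 and vit-5, and the pair puf-3 and puf-11.

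Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on genotype (17217 genes), library sizes were scaled by the trimmed mean of M values (TMM), and 1 quasi-likelihood model with a mean per genotype was fitted to all 15 libraries (glmQLFit, glmQLFTest). A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Errors given as ± after a log2 fold change are standard errors, computed as the absolute log2 fold change divided by the square root of F. CPM values use the TMM-scaled library size and are given as mean ± SD of 3 libraries. Each allele was compared with N2, and each ust allele with ok302; the 3 pairs of ust alleles were also tested. The common biological coefficient of variation was 0.477. Intervals are 95% intervals of this model. A fold against a group with 0 counts in all its libraries was computed against a floor of 3 counts over the group. Such floors cover counting error only, since PCR copies are not independent molecules.

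Gene lists were tested with camera from limma 3.58.1, two-sided, at a preset inter-gene correlation of 0.01, with adjustment over the 28 lists of 1 comparison, and again with an estimated correlation. Counts of list members that passed the test are given after adjustment over all genes and adjusted over the list alone. The lists, fixed before the data were examined, were reported PUF-8 target mRNAs, other PUF-family genes, vitellogenins, major sperm proteins, other sperm genes, oocyte and eggshell genes, germ granule and meiosis genes, cell cycle and DNA replication genes, early embryo genes, molting and larval cuticle genes, adult cuticle collagens, DAF-16 class I and class II genes (targets that DAF-16/FOXO raises or lowers), lipid metabolism genes, mitochondrial stress genes, mitochondrial dynamics and mitophagy genes, heat shock and ER chaperone genes, innate immunity genes, oxidative stress genes, ribosomal proteins, replication histones, mitochondrial genome genes, and markers of neurons, muscle, intestine, hypodermis, sheath and spermatheca, and male soma. The mitochondrial genome list was read as the 12 protein-coding genes of that genome. The symbols msp-71, ssp-11, hsp-16.11 and hsp-16.49 matched no identifier. Some genes stand in more than 1 list: puf-3, puf-5 and puf-11 are also oocyte genes, fbf-1 and fbf-2 are also germ granule genes, and mff-1 and mff-2 are also mitochondrial dynamics genes.

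The rule for named genes was also fixed before the data were examined. It takes puf-8 in every library, and for each allele against N2 the 8 genes in each direction with the largest log2 fold change that were called, had a symbol, a mean of at least 50 counts, and every mutant library beyond every N2 library. It adds up to 4 called members of each list, up to 10 genes per direction called in all 4 alleles, 3 genes per direction for each ust allele against ok302, and all members of the reported PUF-8 targets.

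Alternatives planned before the data were examined were DESeq2 1.42.0, edgeR with DESeq2 size factors (RLE) or with library totals only, no filter or a filter at CPM above 1 in at least 3 libraries, only the 6 libraries of a comparison, the replicate number as a block, a log2 fold change of at least 1, an estimated correlation for lists, and leaving out each library in turn. A test of PUF-binding elements in 3' UTRs was planned and not run, because no genome sequence was used here. Comparisons against the same N2 libraries share their chance values; 20 simulations of unchanged alleles against simulated shared controls gave the overlap without effects. Other splits of the libraries were tested as 10 splits of each comparison and 60 regroupings of all 15 libraries.

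Replicates of a genotype differed by more than counting noise in all 15 pairs (chi-square over degrees of freedom from 13.6 to 313), so each was counted once; separate preparations of 1 RNA sample would differ so too. The labels name no shared culture or day behind the replicate numbers. Deviations of equal-numbered ust221 and ust223 libraries from their group means correlated at 0.14, 0.25 and 0.32, each above the 0.1 taken to mark pairs, so this contrast is given with a replicate block where the block moves it. The tests were checked on counts simulated for ust221 against N2 (17217 genes, 50 genes at each fold). edgeR recovered 1, 4, 22 and 45 genes at 1.5-, 2-, 4- and 8-fold, and DESeq2 recovered 2, 12, 37 and 50. Of 17017 unchanged genes, edgeR called 0 (4.60% had an unadjusted p under 0.05) and DESeq2 called 38. In a second draw of such counts a raised list of 40 genes gave an adjusted p of 3.4e-35 with camera, and an unchanged list gave 0.752. Genes were drawn independently, so this could not show how correlation between genes affects the list test. The simulation was written after the first fits of the real counts.

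After the data were seen, 1 alternative was added. In correlations of log2 CPM, N2 replicate 1 and ust222 replicates 1 and 3 stood apart from the other 12 libraries, and each comparison was fitted again on those 12 (18343 genes). Because ust222 then has 1 library, that library is assumed to vary like the other groups.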

Results

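Levels of puf-8, the gene mutated in these strains, were read first in every library. The 3 ok302 libraries held 7, 11 and 3 counts of puf-8, against 2043, 3899 and 2267 in N2, and the gene fell by log2 -8.67 ± 0.41 (edgeR, adjusted p = 1.9e-07, n = 3 libraries per genotype). In CPM, puf-8 stood at 49.9, 54.6 and 67.1 in ust221, at 73.4, 107 and 65.8 in ust222, at 114.7, 125 and 166 in ust223, and at 79.9, 139 and 123 in N2. None of the 3 ust alleles passed the test against N2 (ust221 -0.99 ± 0.28, adjusted p = 0.0788; ust222 -0.48 ± 0.28, 0.659; ust223 0.25 ± 0.28, 0.943). In ust221 the adjusted p for puf-8 was 0.0188 without N2 replicate 1, 0.011 in the 12 libraries described next, 0.0464 with DESeq2 size factors, 0.0391 with library totals and 0.00229 with DESeq2. Nothing in the labels says whether the 3 libraries of a genotype came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

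Sperm genes split the libraries in a way that crossed genotype. The mean log2 CPM of 30 sperm genes other than the major sperm proteins was -1.54 in N2 replicate 1, and -1.52 and -1.57 in ust222 replicates 1 and 3. The other 12 libraries ranged from 1.36 to 3.48. Mean log2 CPM of 28 molting and larval cuticle genes in the same 3 libraries was 4.66, 4.87 and 4.89, against 2.60 and 2.75 in N2 replicates 2 and 3 and 2.48 in ust222 replicate 2. Correlations of log2 CPM were 0.977 to 0.988 among the 3, 0.792 to 0.905 between them and the rest, and 0.889 to 0.984 within the rest. The same genes stood at 5.67, 6.07 and 5.94 in ok302, at 3.93, 4.18 and 2.85 in ust223, and at 1.64, 3.26 and 1.52 in ust221. Values from the 12 remaining libraries, an alternative chosen after seeing the data, are given for gene groups whose calls against N2 they change, and for some others.

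**Figure D1:**
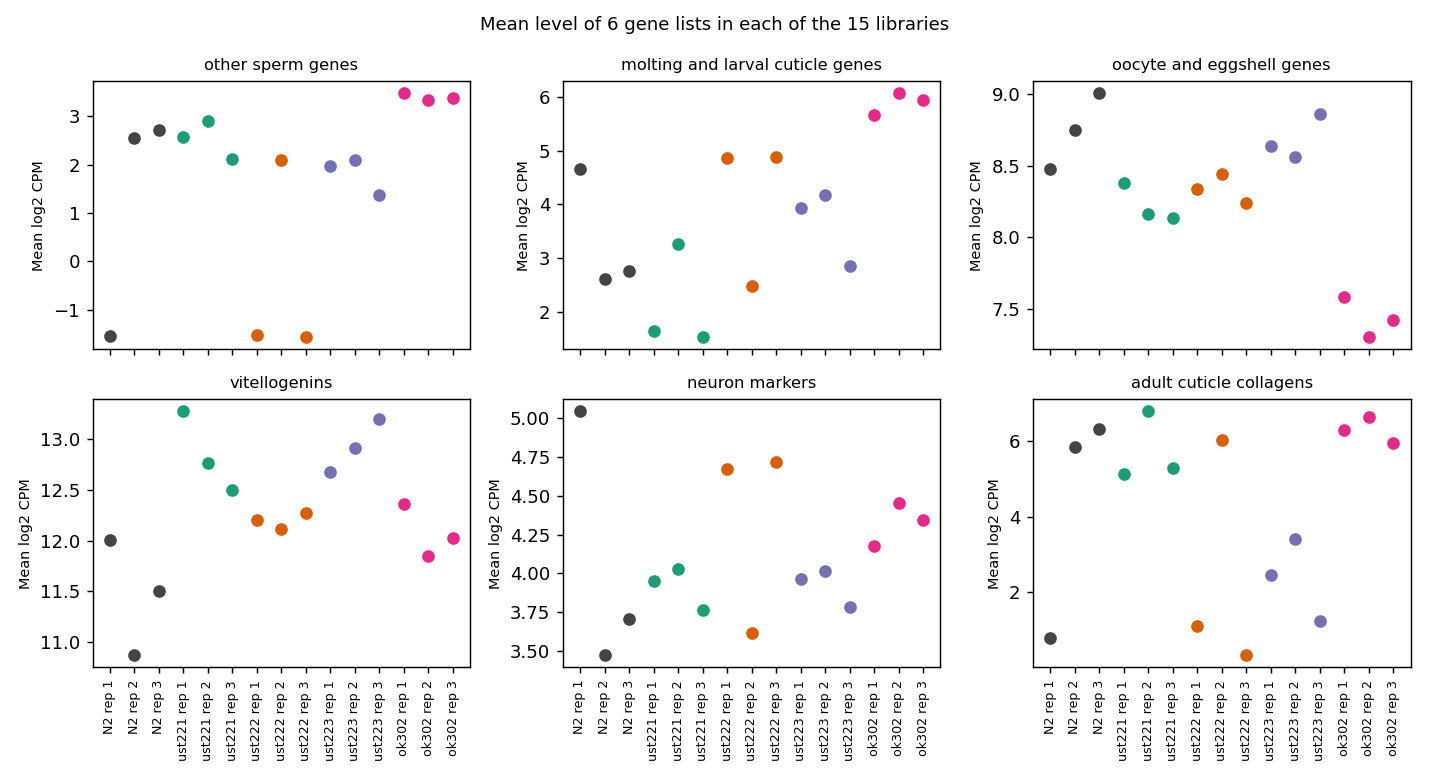
Mean log2 CPM of the genes of 6 lists (vertical axis) in each of the 15 libraries (horizontal axis, grouped by genotype), 1 point per library. Other sperm genes stood at -1.54, -1.52 and -1.57 in N2 replicate 1 and ust222 replicates 1 and 3.

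Transcripts of the female germline were lower in ok302 than in N2. Of 30 oocyte and eggshell genes 28 fell and none rose (28 and 0 adjusted over the list alone; median log2 fold change -1.45, camera adjusted p = 1.3e-31, adjusted p = 0.12 with an estimated correlation). Among them were nos-2, a Nanos-family regulator of germ cells (-2.06 ± 0.17, adjusted p = 4.9e-05; 61.1 ± 4.78 CPM against 254 ± 47.5, n = 3), lin-41, which acts in oocyte growth (-1.81 ± 0.17, 8.9e-05), and oma-2, which acts in oocyte maturation (-1.79 ± 0.19, 0.000116). Germ granule and meiosis genes fell in 19 of 33 cases (22 over the list alone; median -0.86, adjusted p = 1.2e-10, adjusted p = 0.49 with an estimated correlation). They included gld-1, a translational repressor of meiotic germ cells (-1.84 ± 0.30, adjusted p = 0.00111; 235.4 ± 44.4 against 840 ± 315 CPM), and lst-1 (-1.68 ± 0.15, 7.5e-05) and sygl-1 (-1.74 ± 0.16, 8.9e-05), which keep germline stem cells. Cell cycle and DNA replication genes fell in 13 of 16 cases (13 over the list alone; median -1.18, adjusted p = 1.5e-15, adjusted p = 0.12 with an estimated correlation), with the B-type cyclin cyb-3 at -1.81 ± 0.17 and pcn-1, the replication clamp, at -1.51 ± 0.17. Of 9 other PUF-family genes, 5 fell (6 over the list alone; median -1.42, adjusted p = 4.5e-06, adjusted p = 0.20 with an estimated correlation), among them puf-5 (-1.68 ± 0.20, adjusted p = 0.000222). These 4 lists held 28, 30, 15 and 7 falling genes in the 12 libraries.

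Sperm and yolk transcripts did not fall with them in ok302. Of the 30 other sperm genes 5 rose (0 over the list alone; median 1.20, adjusted p = 0.0021, adjusted p = 0.73 with an estimated correlation), and in the 12 libraries the median was 0.62 (adjusted p = 0.0915; 9 rose and 1 fell). Without N2 replicate 1 the list was not called (0.62, adjusted p = 0.17). The 29 major sperm proteins, near-identical copies whose counts are uncertain, had a median of 0.55 (adjusted p = 0.0849, no member called). In the 12 libraries they stood at -0.03, below the 0.39 of all genes. Without N2 replicate 2, N2 replicate 3 or ok302 replicate 3 the list of major sperm proteins was called (0.67, 1.31 and 0.57). The 6 vitellogenins, yolk proteins made in the adult intestine, had a median of 0.45 (adjusted p = 0.239, none called), and 0.93 in the 12 libraries, where 3 rose. Beside the sperm genes, markers of the male soma had a median of 2.28 (1 of 8 rose, the list not called), and 1.93 in the 12 libraries (4 of 9 rose, adjusted p = 0.0748). Their summed level was 31.9, 24.6 and 21.5 CPM in ok302 against 6.38, 4.76 and 7.63 in N2.

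Immune and lipid genes rose in ok302. Of 21 innate immunity genes 11 rose and none fell (12 over the list alone; median 1.65, adjusted p = 2.5e-07, adjusted p = 0.16 with an estimated correlation), with the antibacterial peptide abf-2 at 4.21 ± 0.78 (adjusted p = 0.00215) and sysm-1 at 4.38 ± 0.44 (9.8e-05). Lipid metabolism genes rose in 12 and fell in 5 of 32 cases (14 and 7 over the list alone; median 0.36, adjusted p = 0.0038, adjusted p = 0.29 with an estimated correlation). The stearoyl-CoA desaturase fat-7 rose by 3.28 ± 0.61 (adjusted p = 0.00221; 263 ± 118 against 27.1 ± 12.31 CPM) and the lipases lipl-2 and lipl-1 by 3.06 ± 0.30 and 2.67 ± 0.41, while the acyl-CoA synthetase acs-2 fell by -2.88 ± 0.74 (adjusted p = 0.0132, or 0.0578 with only the 6 libraries). DAF-16 class I genes rose in 3 of 15 cases (2 over the list alone; median 1.01, adjusted p = 0.014, adjusted p = 0.66 with an estimated correlation), among them the superoxide dismutase sod-3 (1.88 ± 0.28, adjusted p = 0.000711). That list was not called without N2 replicate 2 (0.61, adjusted p = 0.15), stood at 1.83 without N2 replicate 1, 0.59 without N2 replicate 3 and 0.65 without ok302 replicate 1, and in the 12 libraries 10 members rose (median 1.83). The lipid median was 0.22 without N2 replicate 1, without ok302 replicate 1 and in the 12 libraries, called each time. The median of all genes in these fits was 0.34, 0.003 and 0.39. In the first and last of them the lipid median thus lay below that of all genes.

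Cuticle genes also rose in ok302, and most of the remaining lists were not called. Molting and larval cuticle genes rose in 8 of 28 cases (8 over the list alone; median 1.29, adjusted p = 9.3e-05, adjusted p = 0.49 with an estimated correlation), with the cuticle collagen bli-2 at 5.60 ± 1.29 (adjusted p = 0.00776). Of the 28, 26 rose in the 12 libraries, with a median of 3.29. Replication histones, whose copies are near-identical, fell in 8 of 38 cases (median -0.61, adjusted p = 0.0044, adjusted p = 0.55 with an estimated correlation), and were not called without N2 replicate 1 (-0.34, adjusted p = 0.12) or in the 12 libraries (-0.34, 0.0696). Lists that were not called included mitochondrial stress genes (median -0.37; 3 of 9 fell, among them the chaperonin hsp-60 at -1.31 ± 0.26 and the import channel gene timm-23 at -0.91 ± 0.20), mitochondrial dynamics and mitophagy genes (-0.45; 4 of 13 fell), heat shock and ER chaperone genes (-0.39; 3 of 17 fell), oxidative stress genes (0.28; 1 rose and 1 fell) and DAF-16 class II genes (0.38; 1 of 8 rose). Medians of the other uncalled lists were -0.66 for early embryo genes, 0.12 for adult cuticle collagens, -0.14 for ribosomal proteins and 0.13 for mitochondrial genome genes. Among markers, neurons stood at -0.02, muscle at 0.04 (2 of 12 rose, among them the myosin gene myo-3 at 1.30 ± 0.20, not called with only the 6 libraries), intestine at 0.34, hypodermis at 0.08 and sheath and spermatheca at 0.28. The male soma list was called without N2 replicate 3 (2.66) or ok302 replicates 2 (2.14) and 3 (2.28), and the ribosomal list without N2 replicate 2 (-0.31) or ok302 replicate 3 (-0.35). In the 12 libraries the neuron markers had a median of 0.82, with 13 of 20 rising (camera adjusted p = 0.0399). Hypodermis markers then stood at 1.32, early embryo genes at 0.30, adult cuticle collagens at -0.45, oxidative stress genes at 0.03, DAF-16 class II genes at -0.01, sheath and spermatheca markers at 0.58 and mitochondrial genome genes at -0.16, none of them called as lists.

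Among the largest rises in ok302 were genes absent from N2. F56A4.3, a gene with a glutathione S-transferase domain, had 0 counts in the 3 N2 libraries and 32.2 ± 8.03 CPM in ok302, at least 772-fold (adjusted p = 0.000312). The receptor L domain gene irld-35 rose at least 123-fold (adjusted p = 0.00263). Both floors take 3 counts over the N2 group and cover counting error only. The 2 genes were also absent or nearly so in the ust alleles. There irld-35 had 0 counts in ust221, ust222 and ust223. F56A4.3 had 0 counts in ust221 and means of 0.014 and 0.091 CPM in ust222 and ust223. Whether the ok302 strain differs from the others in more than puf-8 was not tested. Next to puf-8 itself, the largest fall among the genes named by rule was F01D4.5, with a PHD-like zinc finger (-3.51 ± 0.38, adjusted p = 0.000125). In total 4104 of 17217 genes changed between ok302 and N2, 1454 higher and 2650 lower (edgeR, adjusted p < 0.05, 15 libraries). Scaling by library totals only gave 3530 genes, 1857 higher and 1673 lower, and 2414 genes also had an absolute log2 fold change of at least 1, 1222 higher and 1192 lower. The count was 6918 without N2 replicate 1, 2335 without N2 replicate 3, and 9152 in the 12 libraries (4814 higher, 4338 lower), where 4032 of the 4104 were kept and none turned.

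Lipid, immune and yolk genes rose in ust223. Lipid metabolism genes rose in 9 of 32 cases and none fell (12 over the list alone; median 0.36, adjusted p = 2.7e-13, adjusted p = 0.0122 with an estimated correlation). The palmitoyl-CoA desaturase fat-5 rose by 3.17 ± 0.44 (adjusted p = 0.00296; 154 ± 36.1 against 17.01 ± 7.20 CPM, n = 3) and dgat-2, a diacylglycerol acyltransferase, by 2.25 ± 0.22 (0.000256; 35.97 ± 2.03 against 7.58 CPM). Innate immunity genes rose in 4 of 21 cases (7 over the list alone; median 0.86, adjusted p = 1.9e-13, adjusted p = 0.0294 with an estimated correlation), with sysm-1 at 3.10 ± 0.42 (adjusted p = 0.00247; 130 ± 12.7 against 15.1 ± 1.49 CPM). Vitellogenins rose in 2 of 6 cases (6 over the list alone; median 1.33, adjusted p = 5.0e-12, adjusted p = 0.0318 with an estimated correlation). These 3 lists were the ones called with an estimated correlation in any comparison with N2. Of their members 13, 13 and 5 rose in the 12 libraries, with medians of 0.50, 1.69 and 1.83, and the innate immunity median was 1.70 without N2 replicate 1.

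Other groups moved in ust223 as well. DAF-16 class I genes had 0 called members (3 over the list alone; median 0.67, adjusted p = 6.2e-06, adjusted p = 0.46 with an estimated correlation). Their median was 1.99 without N2 replicate 1, 0.35 and 0.39 without N2 replicates 2 and 3, and 2.03 in the 12 libraries (adjusted p = 1.8e-22; 10 of 15 rose), called each time. Muscle markers (median -0.65; 0 of 12 called, 7 over the list alone, adjusted p = 3.7e-07, adjusted p = 0.14 with an estimated correlation) and ribosomal proteins (median -0.45; 0 of 76 called, adjusted p = 9.5e-17, adjusted p = 0.55 with an estimated correlation) were shifted down as lists. The muscle median was -0.27 without N2 replicate 1 (adjusted p = 0.00594) and -0.26 in the 12 libraries (0.0207). Replication histones fell in 2 of 38 cases (median -0.42, adjusted p = 6.4e-05, adjusted p = 0.46 with an estimated correlation), and were not called without N2 replicate 1 (-0.09, adjusted p = 0.062) or in the 12 libraries (-0.17, 0.0696). The 4 adult cuticle collagens had a median of -2.42 (none called, adjusted p = 0.0405, adjusted p = 0.59 with an estimated correlation). That call was lost without N2 replicate 2 (-2.23, adjusted p = 0.11), N2 replicate 3 (-1.77, 0.23), ust223 replicate 1 (-2.26, 0.062) or ust223 replicate 3 (-2.27, 0.08), and with CPM above 1 (-2.41, 0.0532), with medians near that of all libraries except without N2 replicate 3. Fits of the 12 libraries called it at -2.88 (adjusted p = 1.8e-08; 3 of 4 fell). Oocyte and eggshell genes (-0.08), germ granule genes (-0.09), cell cycle genes (-0.17) and molting genes (-0.23; 1 of 28 fell) were not called. Leaving out N2 replicate 1, the first 3 of these were called at -0.14, -0.27 and -0.19, and the molting genes at 1.96. Leaving out ust223 replicate 3, the first 3 were called at -0.20, -0.28 and -0.25. Major sperm proteins (-0.30) and other sperm genes (-0.35) were not called with all libraries, and were called down at -0.78 and -0.73 without N2 replicate 1. The major sperm proteins were called up without N2 replicate 3 (0.46), and without N2 replicate 2 although their median was -0.18 (adjusted p = 0.0435). Fits of the 12 libraries called both sperm lists down (-0.78 and -0.72), the oocyte (-0.14), germ granule (-0.26), cell cycle (-0.19) and mitochondrial genome (-0.62, adjusted p = 0.00393) lists down, and molting genes (1.96), neuron markers (0.43, 0.0435) and hypodermis markers (0.98, 0.0239) up. Neuron markers were uncalled with all libraries (-0.37), and called at -0.56 and -0.47 without N2 replicates 2 and 3. Male soma markers had a median of 1.34 in ust223 (none of 8 called, adjusted p = 0.0909) and 0.97 in the 12 libraries (0.236), and were called without N2 replicate 3 (1.65), without ust223 replicate 3 (1.64) and with only the 6 libraries (1.43). Their summed level was 13.9, 16.6 and 8.41 CPM, against 6.38, 4.76 and 7.63 in N2.

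**Figure D2:**
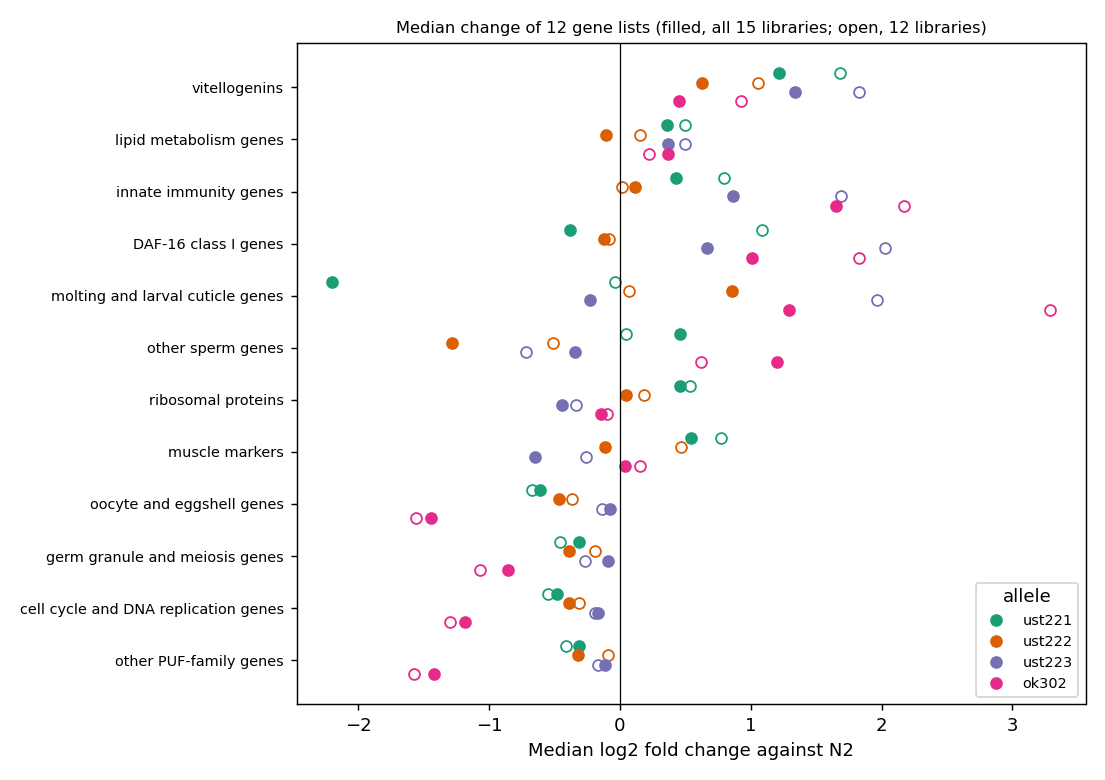
Median log2 fold change against N2 (horizontal axis) of 12 gene lists (vertical axis) in the 4 puf-8 alleles, with filled points for the fit of 15 libraries and open points for the 12. In ok302 the oocyte and eggshell genes stood at -1.45 with 15 libraries.

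Single genes in ust223 showed larger changes. T22B7.7 rose by 7.74 ± 0.48 (adjusted p = 5.7e-06; 171 ± 2.13 against 0.811 ± 0.451 CPM), the short-chain dehydrogenase gene dhs-26 by 6.32 ± 0.74 (0.00117), C38D9.2 by 7.67 ± 0.89 (0.00117) and H39E23.3 by 8.10 ± 1.20 (0.00431). The intestinal protease gene cpr-6 rose by 1.63 ± 0.24 (adjusted p = 0.00431), and dod-23, of the DAF-16 class II list, by 1.71 ± 0.24 (0.00301). Falls that held without each library were C33B4.4 (-2.73 ± 0.26, adjusted p = 0.000241) and dyf-3, a gene of sensory cilia (-2.53 ± 0.31, 0.00144). Altogether 233 genes changed in ust223, 194 higher and 39 lower. The count was 537 without N2 replicate 1, 124 and 112 without N2 replicates 2 and 3, and 94, 85 and 112 without ust223 replicates 1, 2 and 3. With only the 6 libraries of the comparison 32 genes were called, without C38D9.2, cpr-6, dod-23 and dyf-3. It was 360 with library totals, 728 with DESeq2, and 2048 (1439 higher, 609 lower) in the 12 libraries, where 232 of the 233 were kept.

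Oocyte transcripts fell and yolk transcripts rose in ust221. Oocyte and eggshell genes fell in 7 of 30 cases (19 fell and 2 rose over the list alone; median -0.61, adjusted p = 7.0e-13, adjusted p = 0.31 with an estimated correlation), among them mex-6, a zinc finger protein of the early embryo (-0.98 ± 0.16, adjusted p = 0.0158; 175 ± 19.1 against 347 ± 51.1 CPM, n = 3). Cell cycle genes fell in 3 of 16 cases (7 over the list alone; median -0.49, adjusted p = 3.5e-07, adjusted p = 0.31 with an estimated correlation), and the germline stem cell gene lst-1 fell by -0.98 ± 0.15 (adjusted p = 0.0108). Vitellogenins rose in 3 of 6 cases (6 over the list alone; median 1.22, adjusted p = 8.9e-08, adjusted p = 0.31 with an estimated correlation), with vit-1 at 1.96 ± 0.35 (adjusted p = 0.0202; 4882.6 ± 1371 against 1254.3 ± 419 CPM; 0.0538 without N2 replicate 2). Lipid metabolism genes rose in 4 of 32 cases (10 rose and 2 fell over the list alone; median 0.36, adjusted p = 0.00027, adjusted p = 0.31 with an estimated correlation), with dgat-2 at 2.46 ± 0.22 (adjusted p = 0.000331; 41.7 ± 11.7 against 7.58 CPM). In the 12 libraries 18 oocyte and 6 cell cycle genes fell, and 6 vitellogenins and 9 lipid genes rose.

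Further lists were called in ust221 with few single genes past the test. Ribosomal proteins (0.46, or 0.29 to 0.70 with single libraries left out; 0 of 76 called, adjusted p = 9.0e-08, adjusted p = 0.52 with an estimated correlation), muscle markers (0.54; 0 of 12, adjusted p = 0.00073, adjusted p = 0.32 with an estimated correlation) and intestine markers (0.57; 1 of 10 rose, adjusted p = 0.0014, adjusted p = 0.31 with an estimated correlation) were shifted up. Hypodermis markers had a median of -1.41 (2 of 6 fell, adjusted p = 0.00073, adjusted p = 0.31 with an estimated correlation; -0.91 in the 12 libraries). Early embryo genes (median -2.43, adjusted p = 0.00073) and oxidative stress genes (0.36, 0.0149) both stood at an adjusted p of 0.052 without N2 replicate 1, and at 0.32 with an estimated correlation. With single libraries left out, their medians ranged from -2.86 to -1.48 and from 0.44 to 0.66. Molting and larval cuticle genes had a median of -2.20 (adjusted p = 0.0029, adjusted p = 0.48 with an estimated correlation), and -0.04 without N2 replicate 1 (adjusted p = 0.37) and in the 12 libraries. Major sperm proteins (0.57, adjusted p = 0.0086) and other sperm genes (0.46, 0.0179) were called up, at 0.63 with an estimated correlation, and both turned without N2 replicate 1 (0.03 and 0.05, adjusted p = 0.76 for both). Both also lost the call without ust221 replicate 2 (0.052 and 0.063). Germ granule genes were called at -0.31 (adjusted p = 0.0166, adjusted p = 0.63 with an estimated correlation), but not without N2 replicate 2 (-0.05, 0.31), N2 replicate 3 (-0.19, 0.33) or ust221 replicate 2 (-0.08, 0.15), and stood at -0.08 without ust221 replicate 1 and at -0.46 in the 12 libraries (8 fell), called in both.

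Calls of 4 more lists in ust221 ended when single libraries were left out, some of them with medians as large as before. DAF-16 class II genes (median 0.64, adjusted p = 0.0365, adjusted p = 0.48 with an estimated correlation) were lost without N2 replicate 1 (median 0.30, adjusted p = 0.50) or ust221 replicate 2 (0.75, 0.052), and stood at 0.97 without N2 replicate 3. Innate immunity genes (0.43, adjusted p = 0.0365, adjusted p = 0.48 with an estimated correlation) were lost without N2 replicates 2 (0.34, 0.22) and 3 (0.21, 0.091) or ust221 replicates 1 (0.38, 0.11) and 2 (0.52, 0.063). That list was called at 0.78 without N2 replicate 1 (adjusted p = 0.00803) and at 0.79 in the 12 libraries (0.00507; 3 rose). Replication histones (-0.42, adjusted p = 0.0132, adjusted p = 0.48 with an estimated correlation) were lost without N2 replicate 1 (-0.32, 0.24) or ust221 replicate 3 (-0.20, 0.30). Mitochondrial genome genes (0.40, adjusted p = 0.0489, adjusted p = 0.63 with an estimated correlation) were lost without N2 replicates 1 (0.23, 0.50) and 3 (0.44, 0.059) or ust221 replicates 2 (0.47, 0.063) and 3 (0.39, 0.19), and stood at 0.82 and 0.68 without N2 replicate 2 and ust221 replicate 1. DAF-16 class I genes were not called (-0.38), but had a median of 1.09 without N2 replicate 1 (adjusted p = 0.0014), and 8 of 15 rose in the 12 libraries. Neuron markers stood at -0.33 (adjusted p = 0.263), at -0.69 without N2 replicate 2 (0.0081) and at 0.45 in the 12 libraries (0.024). Other PUF-family genes (-0.41, adjusted p = 0.037), heat shock genes (0.54, 0.0333), and sheath and spermatheca markers (0.61, 0.0219) were called in the 12 libraries but not in all 15, and the first of these also with other scalings and filters. The 12 libraries lost the calls of DAF-16 class II genes (0.30, adjusted p = 0.547), histones (-0.29, 0.13) and mitochondrial genome genes (0.23, 0.331).

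T22B7.7 again gave the clearest rise in ust221, by 6.56 ± 0.46 (adjusted p = 2.6e-05; 75.9 ± 19.8 against 0.811 ± 0.451 CPM). C38D9.2 rose by 5.42 ± 0.82 (adjusted p = 0.0109), F40D4.13 by 4.79 ± 0.68 (0.00862), dhs-26 by 4.45 ± 0.69 (0.0124) and C08F11.7 by 3.96 ± 0.49 (0.00382). Falls named by rule included hch-1, a gene with an astacin protease domain (-8.89 ± 1.69, adjusted p = 0.0244; -6.69 in the 12 libraries), which was not called without ust221 replicates 1 (0.0734) and 2 (0.0906). They also included the cuticle collagen dpy-14 (-6.93 ± 1.52, adjusted p = 0.038; -4.07 and 0.000209 in the 12 libraries), which was not called without N2 replicate 3 (0.0524) or ust221 replicates 1 (0.114), 2 (0.124) and 3 (0.0646). In all, 308 genes changed in ust221, 177 higher and 131 lower. Leaving out N2 replicates 1, 2 and 3 gave 1482, 100 and 83 genes, and leaving out ust221 replicates 1, 2 and 3 gave 170, 117 and 605. Only T22B7.7 remained with the 6 libraries of the comparison, while DESeq2 called 2101 genes, DESeq2 size factors in edgeR 732, no filter 525, the stricter filter 517, the replicate block 162, and library totals 1133 (204 higher, 929 lower). In the 12 libraries 2503 genes changed, 1283 higher and 1220 lower, among them 307 of the 308.

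In ust222, T22B7.7 alone passed the test. It rose by 5.12 ± 0.43 (edgeR, adjusted p = 0.000305; 27.9 ± 11.01 against 0.811 ± 0.451 CPM, n = 3), while 1376 of 17217 genes had an unadjusted p under 0.05. With only the 6 libraries of the comparison its adjusted p was 0.99994. Levels of dgat-2 were 18.5, 19.01 and 21.1 CPM in ust222 and 7.59, 7.58 and 7.58 in N2, without passing the test (1.36 ± 0.22, adjusted p = 0.093). The count of changed genes was 962 without N2 replicate 1, 607 without ust222 replicate 2, 88 with DESeq2, 2 with library totals and 3 in the 12 libraries, where ust222 has 1 library.

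**Figure D3:**
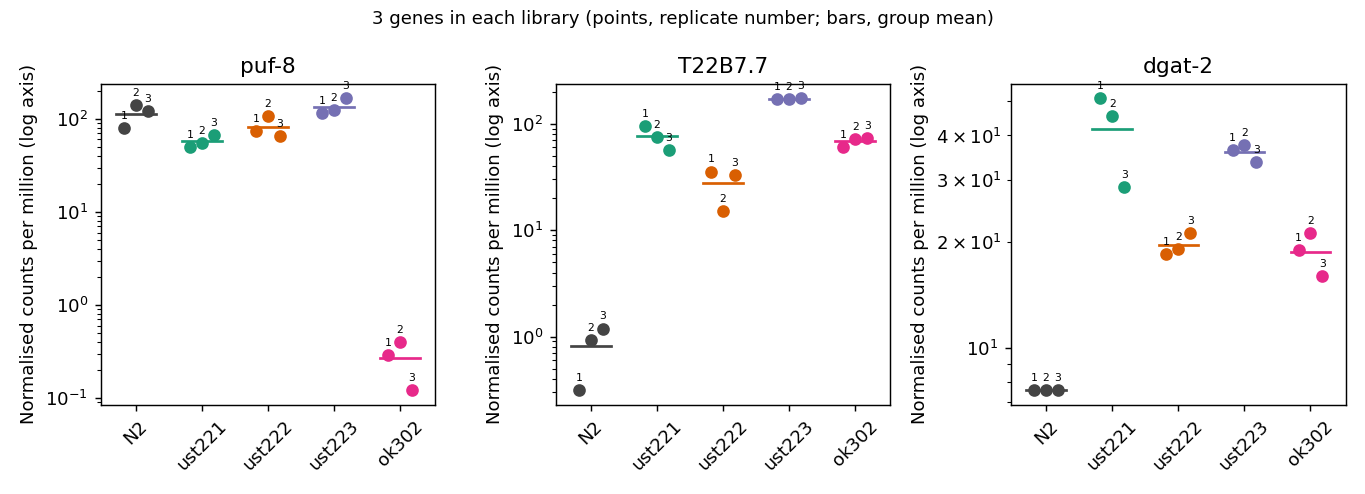
Normalised CPM (vertical axis, log scale) of puf-8, T22B7.7 and dgat-2 in each library, 1 point per library numbered by replicate, with a bar at the mean of each genotype (horizontal axis). T22B7.7 stood at 0.313, 0.930 and 1.19 CPM in N2, and at 35.6, 15.2 and 32.7 in ust222.

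No list in ust222 held a called gene, and 12 of 28 lists were called by camera. Adjusted over the list alone, 8 oocyte, 5 cell cycle, 2 germ granule, 1 other sperm and 1 histone gene fell, and 1 vitellogenin and 1 lipid gene rose. Vitellogenins (median 0.63, adjusted p = 4.6e-06; 1.06 in the 12 libraries), molting genes (0.86, 2.5e-05; 0.07 in the 12), innate immunity genes (0.11, 0.01; 0.02 in the 12), ribosomal proteins (0.05, 0.0081) and neuron markers (0.10, 0.0173; 0.28 in the 12) were called up, and lipid metabolism genes were called up with a median of -0.11 (0.0466). Major sperm proteins (-1.70, adjusted p = 4.6e-06; -0.59 in the 12), other sperm genes (-1.28, 7.1e-05; -0.51 in the 12), oocyte genes (-0.47, 1.4e-09), germ granule genes (-0.39, 7.1e-05; -0.19 in the 12), cell cycle genes (-0.39, 1.6e-05) and replication histones (-0.28, 0.0472; -0.26 in the 12) were called down. The 12 libraries lost the calls of molting (adjusted p = 0.945), innate immunity (0.797), neuron (0.255), other sperm (0.0647), germ granule (0.188) and histone (0.0733) lists, and kept the other 6. They gained early embryo genes (-2.14, adjusted p = 0.032), muscle markers (0.47, 0.00277) and sheath and spermatheca markers (0.42, 0.0288). All 12 had an adjusted p of at least 0.558 with an estimated correlation. Leaving out ust222 replicate 2 took the sperm medians to -9.44 and -4.94, and leaving out N2 replicate 1 took those of molting genes to 3.47, vitellogenins to 1.29, neuron markers to 1.25 and innate immunity genes to 0.80. At the weakest, medians with a single library left out were -0.97 for major sperm proteins, -0.83 for other sperm genes and -0.18 for germ granule genes. Calls were lost for both sperm lists without N2 replicate 3 (adjusted p = 0.055 for both), for germ granule genes without ust222 replicate 3 (0.065), and for ribosomal proteins without N2 replicate 2 (-0.11, 0.53). Lipid genes lost theirs without N2 replicate 2 (0.27), N2 replicate 3 (0.054) or ust222 replicate 2 (0.13), and innate immunity genes without N2 replicate 2 (0.12), ust222 replicate 1 (0.098) or ust222 replicate 3 (0.10). Histones lost theirs without N2 replicates 1 (0.72) and 3 (0.055) or ust222 replicate 2 (0.56), and also with no filter (0.053), CPM above 1 (0.070) or only the 6 libraries (0.0986). Neuron markers lost theirs without N2 replicates 2 (0.90) and 3 (0.28) or ust222 replicates 1 (0.29) and 3 (0.43).

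Against ok302, all 3 ust alleles held more female germline transcripts. Oocyte and eggshell genes were higher in 22, 26 and 27 of 30 cases in ust221, ust222 and ust223 (26, 26 and 30 over the list alone; medians 0.86, 0.97 and 1.28, adjusted p = 2.4e-15, 7.6e-23 and 9.5e-33, adjusted p = 0.25, 0.23 and 0.15 with an estimated correlation), and none was lower. Cell cycle genes were higher in 11, 11 and 13 of 16 cases (12, 12 and 13 over the list alone, adjusted p = 1.7e-07, 7.1e-11 and 3.6e-14, adjusted p = 0.25, 0.23 and 0.15 with an estimated correlation). Germ granule genes were higher in 15, 8 and 17 of 33 (19, 13 and 20 over the list alone, adjusted p = 3.1e-08, 6.6e-07 and 7.4e-11, adjusted p = 0.51, 0.69 and 0.53 with an estimated correlation). Levels of puf-8 differed by 7.68 ± 0.40, 8.20 ± 0.41 and 8.92 ± 0.42 (edgeR, adjusted p = 6.4e-07, 3.4e-07 and 1.5e-07). Innate immunity genes were lower than in ok302 in 8, 8 and 4 of 21 cases (11, 10 and 5 over the list alone, adjusted p = 9.7e-06, 6.4e-06 and 0.16, adjusted p = 0.24, 0.23 and 0.71 with an estimated correlation). Molting genes were lower in 19, 7 and 8 of 28 (25, 9 and 10 over the list alone, adjusted p = 4.4e-12, 0.047 and 2.8e-06, adjusted p = 0.24, 0.69 and 0.44 with an estimated correlation). The short-chain dehydrogenase gene dhs-25 was higher in ust221 than in ok302 (3.71 ± 0.83, adjusted p = 0.013), and the lectin gene clec-210 higher in ust223 (4.98 ± 0.55, 0.000477; 10.2 ± 2.86 against 0.320 ± 0.0882 CPM).

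These contrasts called 2878 genes in ust221 (1870 higher, 1008 lower), 2904 in ust222 (1312 and 1592) and 3054 in ust223 (2093 and 961), all against ok302. With library totals the split was 364 and 1582 in ust221 and 1580 and 1148 in ust223, and at an absolute log2 fold change of at least 1 it was 663 and 954, 394 and 1413, and 801 and 819. For ust222 more genes were higher than lower with DESeq2 size factors (2027 and 1658), no filter (2088 and 1329), CPM above 1 (1724 and 1458) or only the 6 libraries (1215 and 1163), and in the 12 libraries (2967 and 2841). The same held without ust222 replicates 1 (752 and 638) and 3 (2487 and 718) or ok302 replicates 1 (2350 and 790) and 3 (2296 and 801), while leaving out ust222 replicate 2 gave 1146 and 3166. Counts for ust221 were 722 and 1262 without ust221 replicates 1 and 2, and 1323 without ok302 replicate 2. For ust222 they were 1390 without ust222 replicate 1 and 1632 without ok302 replicate 2. For ust223 they were 1702, 2035 and 1387 without ust223 replicates 1, 2 and 3, and 1701 without ok302 replicate 2. DESeq2 called 4430, 4995 and 4625 genes, and the 12 libraries 7525, 5808 and 7845. Fits of only the 6 libraries compared called 6515 in ust221 (2944 higher, 3571 lower) and 8972 in ust223 (4313 and 4659).

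T22B7.7 was the only gene called in the same direction in all 4 alleles against N2 (ok302 6.42 ± 0.46, adjusted p = 1.6e-05), and it rose in each. DESeq2 called 38 such genes, library totals 2 and the separate fits of 6 libraries 0. The count was 98 without N2 replicate 1, 19 without ust222 replicate 2, 2 without ust221 replicate 3 and 2 in the 12 libraries. Leaving ust222 aside, 72 genes changed in the same direction in ust221, ust223 and ok302, 69 higher and 3 lower, where independent lists would share 0.168 and 0.0457. They included dgat-2, the desaturases fat-1, fat-2 and fat-4, the acyl-CoA oxidase acox-1.2, the cytochrome P450 cyp-35A2 and pud-3 and pud-4 among the rises, and clec-88, cpg-8 and grif-1 among the falls. These were picked after their values were seen. In the 12 libraries more genes were shared in both directions, and falls made up a larger share of them. All 3 comparisons share the 3 N2 libraries, which are too few to divide, so part of the overlap may come from shared controls. In 20 simulations of unchanged alleles against shared controls, ust221 and ust223 had the same sign in a median of 66.7% of genes, with 0 genes called in both. The share in the real counts is not given here, so the 66.7% is no test of the overlap.

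Reported PUF-8 targets fell in 2 of 6 cases in ok302 and rose in 1 (2 and 1 over the list alone, camera adjusted p = 0.13), and 4 fell in the 12 libraries. The homeobox gene pal-1 fell by -1.28 ± 0.28 (adjusted p = 0.00627; 59.7 ± 3.37 against 145 ± 60.8 CPM) and mff-2, which acts in mitochondrial fission, by -1.20 ± 0.26 (0.00546). The transcription factor gene pqm-1 rose by 1.42 ± 0.41 (adjusted p = 0.0245), and was not called without N2 replicates 2 (0.0884) and 3 (0.105) or ok302 replicates 1 (0.128) and 3 (0.147), or with only the 6 libraries (0.109). The other members stood at -0.59 (mff-1), -0.58 (farl-11) and -0.51 (let-60), and the last 2 were called without N2 replicate 1 (adjusted p = 0.0343 and 0.0483). As a list the 6 genes were called in ust221 alone (median -0.38, adjusted p = 0.0365, adjusted p = 0.32 with an estimated correlation), and not without N2 replicates 2 (0.12) and 3 (0.089) or ust221 replicates 1 (0.10) and 2 (0.063). With single libraries left out, that median ranged from -0.65 to -0.20, and it was -0.50 in the 12 libraries. Medians in ust222, ust223 and ok302 were -0.38, -0.19 and -0.58. No member was called in the ust alleles, where pqm-1 stood at 0.12, 0.36 and 0.92 (in ust223 1.54 in the 12 libraries, adjusted p = 0.00137). In ust221 pal-1 stood at -0.88 (adjusted p = 0.107, or 0.0127 without N2 replicate 1). The study may have chosen pqm-1 from these libraries, so this list may not be independent evidence.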

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

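The tests of the 3 patterns weighed below, on libraries that stand apart, on oocyte genes in ok302 and on the genes shared by 3 alleles, were chosen only after the results were seen.

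A difference between alleles drew attention to 9 results, each a direct edgeR or camera test of 1 allele against another. They were picked because their calls against N2 went in opposite directions and the direct test was called. The same libraries served for both steps, so the direct p-values are not independent support. Between ust221 and ust222 the medians of the direct log2 difference were 2.28 for major sperm proteins, 2.01 for other sperm genes and -3.19 for molting and larval cuticle genes (adjusted p = 4.6e-09, 2.6e-07 and 1.3e-08; adjusted p = 0.55 for all 3 with an estimated correlation), with no single member called. Mean log2 CPM in ust222 replicates 1, 2 and 3 was -2.81, 4.72 and -2.75 for the first list, -1.52, 2.09 and -1.57 for the second and 4.87, 2.48 and 4.89 for the third. In ust221 the 3 lists stood at 5.48, 5.85 and 4.35, at 2.57, 2.90 and 2.12, and at 1.64, 3.26 and 1.52, so replicate 2 of ust222 lay within, just below and within the values of ust221. Between ust221 and ust223 ribosomal proteins differed by 0.90 (11 of 76 members called, or 1 with the replicate block; adjusted p = 2.0e-32, adjusted p = 0.42 with an estimated correlation) and muscle markers by 1.09 (7 of 12; adjusted p = 2.3e-13, adjusted p = 0.080 with an estimated correlation). Ribosomal proteins differed by 0.50 between ust222 and ust223 (none of 76 called; adjusted p = 2.2e-26, adjusted p = 0.51 with an estimated correlation). Against ok302, molting genes stood at -3.97 in ust221 (19 of 28 called; adjusted p = 4.4e-12, adjusted p = 0.24 with an estimated correlation) and other sperm genes at -2.365 in ust222 (7 of 30; adjusted p = 4.8e-08, adjusted p = 0.69 with an estimated correlation; ok302 libraries at 3.48, 3.33 and 3.37). The lectin gene clec-210 rose in ust223 (2.67 against N2) and fell in ok302 (-2.31), a direct difference of 4.98 ± 0.55 (edgeR, adjusted p = 0.000477).

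N2 replicate 1 and ust222 replicates 1 and 3 were far lower in sperm transcripts than the other 12 libraries. They were higher in molting genes than the other N2 and ust222 libraries, though not than ok302, and 2 technical explanations were tested. Collection before adulthood predicts low yolk transcripts, but the lowest vitellogenin level of the 3 was 12.01 in mean log2 CPM, above N2 replicates 2 and 3 at 10.87 and 11.51, which argues against it for all animals of a library, while adult cuticle collagens at 0.77, 1.11 and 0.33, against 5.84 and 6.34 in those N2 libraries, leave a mix of stages open. Only collection before adulthood was tested, so other differences in age, including a later age of these animals, stay open. An exchange of the labels of N2 replicate 1 and ust222 replicate 2 would put like with like. At a gap of at least 1 in log2 CPM, 2 genes separated N2 from the other 12 libraries after the exchange and 2 as given, so this count cannot tell the 2 readings apart. The 2 genes as given were T22B7.7 and dgat-2. T22B7.7 stood at 0.313 CPM in the first and 15.2 in the second of these libraries, against 0.930 and 1.19 in N2 replicates 2 and 3. Levels of dgat-2 were 7.59 and 19.01, against 7.58 and 7.58. In ust222 replicates 1 and 3, which the exchange leaves in place, T22B7.7 stood at 35.6 and 32.7 CPM and dgat-2 at 18.5 and 21.1. In both genes N2 replicate 1 was close to or below the other N2 libraries, and ust222 replicate 2 was nearer to the other ust222 libraries. For these 2 genes the values argue against an exchange, though both were found with the labels as given. The 2 genes that separated N2 after the exchange go the other way. At gaps of 0.5 and 0.25 the exchange gave 29 and 175 genes against 17 and 45, while the largest gap was 3.22 as given and 1.28 after it (fipr-24); this test was settled after several tries, and a further test whose genes had been picked with the labels as given was set aside. Genotype as the biological explanation was not tested, since the 3 libraries carry 2 genotypes.

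Oocyte and eggshell genes fell in ok302 with a median of -1.45, and 2 other readings than a change within the germline were tested. Fewer adult hermaphrodites among the animals collected would lower yolk transcripts too, but the vitellogenin median was 0.45. The 95% intervals of all 6 vitellogenins lay above the oocyte median (lowest bound -0.88), though vit-3, vit-4 and vit-5 are near-identical copies. That alone does not exclude fewer adults, since yolk transcripts rose in other alleles (median 1.69 in ust221 and 1.83 in ust223 in the 12 libraries). In the same fit molting genes stood at 3.29 in ok302, which would go with fewer adults, and adult cuticle collagens at -0.45. A smaller germline with unchanged proportions of its cells would lower sperm genes as well. Their median was 0.62 in the 12 libraries and 1.20 in all 15, where the median of all genes was 0.39 and 0.10. Major sperm proteins stood at -0.03 in the 12, below the median of all genes. These values do not exclude a smaller germline. Male soma markers were also higher in ok302 (summed CPM 21.5 to 31.9, against 4.76 to 7.63 in N2), and more males could bring sperm transcripts of their own. Also open is the biological explanation, a change tied to the ok302 allele, tested only by the contrast with N2 itself.

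The 72 genes called in the same direction in ust221, ust223 and ok302 share their N2 libraries. In 20 simulations of unchanged alleles against shared controls, the highest number of such genes was 0, but no 2 of the 3 simulated alleles shared a called gene either, so chance values of the controls stay open. N2 replicate 1 standing apart would end the calls once it is left out, but 72 of the 72 were called in the same direction in all 3 alleles without the 3 libraries. These calls therefore did not need that library. Nearly all calls of these alleles against N2 were kept in that fit, as given above, so the test could hardly have come out otherwise. N2 replicates 2 and 3 are still shared there. The biological explanation, an effect common to the puf-8 alleles, has no further test here.

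Other splits of the same libraries were called with the same test. For ust221, 2 of 10 splits gave at least as many genes as the 308 of the real one, with 1242 as the highest other, and for ust222 2 of 10 reached the real 1, with 9808 as the highest other. In both comparisons the highest split put N2 replicate 1 with 2 libraries of the allele. For ust222 these were replicates 1 and 3, which stand apart together with it. For ust221 they were replicates 1 and 2, which correlated with N2 replicate 1 at 0.826 and 0.815, against 0.837 for replicate 3. Likeness of the libraries thus does not account for the ust221 split. In ust223 and ok302 against N2, 1 of 10 splits reached the real counts of 233 and 4104, with 1 and 0 genes as the highest others. Against ok302 the same held for ust221, ust222 and ust223, each with 1 of 10 and 0 as the highest other. With 10 splits no share under 0.05 is possible. Of 60 regroupings of all 15 libraries, 1, the real one, gave a gene called in all 4 alleles, and the highest other gave 0.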

How the results depend on the processing

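Fits of 12 libraries, chosen after seeing the data, were the 1 alternative added to those planned; a test of PUF-binding elements and of looser cores in 3' UTRs was planned and not run, since no genome sequence was used here. Numbers of changed genes are given in the order ust221, ust222, ust223 and ok302 against N2, then ust221, ust222 and ust223 against ok302, then all 4 alleles (308, 1, 233, 4104, 2878, 2904, 3054 and 1). DESeq2 gave 2101, 88, 728, 5436, 4430, 4995, 4625 and 38. With only the 6 libraries compared the counts were 1, 0, 32, 2980, 6515, 2378, 8972 and 0. The higher counts than with all libraries were those of ust221 and ust223 against ok302, whose fits held none of the 3 libraries that stand apart. Every comparison with a lower count held at least 1 of those libraries. The cause was not tested further. Library totals gave 1133, 2, 360, 3530, 1946, 3056, 2728 and 2, and DESeq2 size factors 732, 1, 279, 4346, 3102, 3685, 3350 and 1. No filter gave 525 and CPM above 1 in at least 3 libraries 517 in ust221. An absolute log2 fold change of at least 1 left 204, 1, 210, 2414, 1617, 1807, 1620 and 1, by its construction. The 12 libraries gave 2503, 3, 2048, 9152, 7525, 5808, 7845 and 2. Leaving out each library gave ranges of 83 to 1482, 1 to 962, 85 to 537, 2335 to 6918, 722 to 2561, 1390 to 4312, 1387 to 2862 and 1 to 98. Of 112 list tests against N2 49 were called, 3 with an estimated correlation, 52 in the 12 libraries and 42 to 55 when each library was left out. Unless the construction shows it, the cause was not tested.

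With the replicate block the counts were 162, 1, 202, 3767, 2441, 2806, 2689 and 1; it ended 27 calls of named genes and no list call, turned none, added the list calls of mitochondrial genome genes in ust222 (-0.49, adjusted p = 0.0028) and ust223 (-0.36, 0.031) and of DAF-16 class I genes in ust222 (-0.08, 0.0487), and moved no other count by over 1.5 times. Between ust221 and ust223 the block lowered the count from 647 to 477 genes and changed no list call. Elsewhere the samples share only a number by the rule used: ust222 and N2 libraries of equal number correlated at 0.78, 0.73 and -0.64, and those of the 8 other comparisons at -0.23 to 0.15, in none of them above 0.1 for all 3 numbers. As a hint from the data, 10 of 15 libraries correlated best with a library of their own number, which 4 of 12 possible partners carried.

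In the 12 libraries 10 list results turned: in ust221 major sperm proteins (0.0326), other sperm genes (0.0458) and neuron markers (0.45), in ust222 molting genes (0.0654) and innate immunity genes (0.0175), and in ust223 major sperm proteins (-0.78), other sperm genes (-0.72), molting genes (1.96), neuron markers (0.43) and hypodermis markers (0.98). Leaving out single libraries, major sperm proteins ranged from 0.0329 to 1.29 in ust221 and from -0.78 to 0.46 in ust223, other sperm genes from 0.0516 to 0.88 and from -0.73 to 0.13, molting genes in ust223 from -0.66 to 1.96, and ribosomal proteins in ust222 from -0.11 to 0.32. The first 3 turned without N2 replicate 1 and the last without N2 replicate 2; the test's direction is counted here, and some medians kept their sign. No named gene turned. Of 192 results for named genes, 168 of them called, calls were lost for 79 with only the 6 libraries, 10 with no filter, 9 with library totals, 8 with DESeq2 size factors, 1 in the 12 libraries (col-121) and 0 with DESeq2. Of the 150 called against N2, 10, 52 and 64 were lost without N2 replicates 1, 2 and 3. Other scalings changed the sign of medians of lists: lipid genes in ust222 from -0.11 to 0.01 (DESeq2 size factors) and 0.03 (totals), and with totals oocyte and germ granule genes in ust223 from -0.08 and -0.09 to 0.02 and 0.03, heat shock genes in ust221 from 0.09 to -0.17, muscle markers in ust222 from -0.11 to 0.01, and neuron markers and ribosomal proteins in ok302 from -0.02 and -0.14 to 0.17 and 0.07. With totals the median of all genes moved from -0.09 to -0.34 in ust221, from 0.10 to 0.30 in ok302, and from -0.11 to -0.56 in ust221 against ok302. DESeq2 size factors gave 2027 higher and 1658 lower genes in ust222 against ok302. In counts simulated for ust221 against N2, 22 of 50 genes changed 4-fold were recovered, so smaller changes were mostly missed in that setting. This does not carry over to ok302 against N2. There 2414 of the 4104 called genes had an absolute log2 fold change of at least 1, and the others a smaller one.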

Other observations

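The tests of gene families, of the X chromosome and of the window around puf-8 were chosen only after the results were seen. All are Fisher tests that count genes as independent, and none allows for correlation between genes. Estimating that correlation took the list calls against N2 from 49 to 3.

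Genes of nuclear pores, translation initiation and mitochondrial ribosomes fell in ok302 beyond the lists fixed at the start, where oocyte (28 of 30), germ granule (19 of 33) and cell cycle genes (13 of 16) fell and cytosolic ribosomal proteins were not called (median -0.14). Of all 17217 tested genes 2650 fell. Of 26 nucleoporin genes of the npp family 21 fell (1-sided Fisher test against all genes with a symbol, adjusted p = 2.6e-10 over 552 tests of families), with npp-9 at -1.31 ± 0.20 (edgeR, adjusted p = 0.00074). Translation initiation factor genes of the eif family fell in 14 of 25 cases (adjusted p = 0.000464), with eif-3.K at -1.02 ± 0.18. Mitochondrial ribosomal protein genes fell in 14 of 29 (mrps, adjusted p = 0.00326) and 16 of 41 cases (mrpl, 0.0107), with mrps-28 at -1.39 ± 0.24. Mediator subunit genes (mdt) and small GTPase genes of the rab family each fell in 11 of 20 cases (adjusted p = 0.00372 for both), among them rab-7, which acts in late endosomes (-1.34 ± 0.17).

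Transthyretin-related, saposin-like, carboxylesterase and cytochrome P450 genes rose in ok302. Of all 17217 tested genes 1454 rose. Of 53 ttr genes 20 rose (Fisher test, adjusted p = 6.9e-07), with ttr-29 at 2.70 ± 0.28 (edgeR, adjusted p = 0.000116). Saposin-like genes of the spp family rose in 11 of 24 cases (adjusted p = 0.000188), with spp-15 at 1.69 ± 0.32, and carboxylesterase genes (cest) in 12 of 31 (0.000405). Cytochrome P450 genes rose in 18 of 67 cases (adjusted p = 0.000464), with cyp-35B1 at 2.59 ± 0.39.

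Genes on the X chromosome fell less often than others in ok302: 5.93% of them against 16.9% of autosomal genes (Fisher test, odds ratio 0.309, adjusted p = 7.4e-52). Whether the fall of the germline lists accounts for this was not tested. In ust221, 1.83% of X-linked and 0.898% of autosomal genes rose (adjusted p = 0.000337), and 0.373% and 0.824% fell (0.0316). In ust223, 0.249% and 0.223% fell (0.816). Within 500 kb of puf-8, 65 of 217 genes changed in ok302, 29.95% against 23.8% elsewhere (adjusted p = 0.111). C30G12.2, a gene close to this locus that was picked after its values were seen, was called in ust221 (3.02), ust223 and ok302. Strand was not stated, so counts of overlapping genes in this window are uncertain.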
